A study of Mus musculus with 2 samples.

How the data were processed

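Chromatin immunoprecipitation with an antibody to REST, followed by sequencing (ChIP-seq), was done on placentae of wild-type C57BL/6 mice at gestation day 15, with the day of the vaginal plug counted as day 0.5, per the labels' protocols. Placentae of 3 biological replicates were pooled before immunoprecipitation for each of 1 library labelled male and 1 labelled female, per the labels' protocols, so each sex has 1 library and no replicates. Reads were checked with FastQC, aligned with Bowtie2 to GRCm38.p5 and peaks were called with MACS2, per the submitters' processing notes. The versions, the calling parameters, the handling of duplicate reads and the control are not given in the sources used here.

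Each library has 1 deposited peak list, called per library. The deposited fold enrichment of a peak is the ratio of its ChIP pileup to the caller's local background, as the authors' peak caller gave it. The authors' −log10 p and −log10 q belong to the same summit, and the lowest −log10 q was 1.30 in the male and 1.31 in the female list. These values are the authors' and were used to describe, rank and filter peaks within a list. Peaks on chromosomes 1 to 19, X and Y were kept, and the mitochondrial peaks were set apart. Overlapping intervals of a list were to be merged into regions, but 0 intervals overlapped in either list, so each peak is 1 region. Coordinates were written counting from 1.

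The peak lists give no read totals. Fragments at each summit and the control pileup were therefore recovered from the deposited fold and −log10 p, with MACS2's definitions (a pseudocount of 1 in the fold and a Poisson tail for p). The scale factor between ChIP and control was taken as the largest one at which the recovered pileups were whole numbers of fragments. With a tolerance of 0.01 fragments, 100% of the peaks of both lists were whole, at factors of 0.833 (male) and 0.854 (female). Among factors that were not divisors of these, the best made 51.7% of the low peaks whole in each list. The step of the control pileup in windows of 1 kb gave fragment lengths of 180 bases (male) and 171 bases (female), which were also the narrowest widths in the lists. The lowest control pileup per base of fragment length was 0.0178 in both. With MACS2's default mouse genome size, assumed here, this stands for 33.2 M control reads in both lists, 39.9 M male and 38.9 M female ChIP reads. The male to female ratio of depth was 1.02. The recovery was tested on simulated peaks, where 100% of the fragment numbers were right.

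The highest number of fragments at a summit was 360 in the male and 342 in the female list, exactly 2 times the fragment length, and 0 regions lay above it. This is the most that can lie over a base when 1 read per position and strand is kept. In the male list 4.94% and in the female list 5.86% of the regions lay over 50% of this ceiling, so the fold of the tallest regions is compressed. To compare the libraries, fragments were divided by depth and by fragment length ("scaled fragments"); in an added calculation the ceiling was undone by assuming reads fell on positions at random.

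Gene names and positions came from a RefSeq gene table of GRCm38.p6, whose primary chromosomes have the same coordinates as GRCm38.p5; it holds 49943 genes on the chromosomes used, 21887 of them protein-coding. The table gives the span of each gene, without strand, exons or transcripts. The planned transcription start sites were therefore replaced by either annotated end of a gene, and exons, introns and untranslated regions were not told apart. A genome sequence was not used here, so the planned search for the RE1 motif and the removal of repeats were not run.

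Regions of the lists were called shared at an overlap of 1 base or more. The overlap by chance came from 1000 random placements on the same chromosome. Where several regions met, each was paired once, taking pairs in descending order of the lower of both folds. For the part of the fold correlation that the shared control gives, female fragments were permuted over these regions 1000 times, a calculation added after the data were seen. A gene was covered by a region whose summit lay inside it or within 5 kb of an end. The 12 gene lists were fixed before the data were examined, all their members were found in the table, and a gene can belong to several lists. Each list's coverage was set against 10000 random lists of protein-coding genes matched on gene length in 20 bins, as a description of these libraries. On simulated data, the overlap count found 1000 of 1000 regions removed on purpose, the list percentiles of random lists had a mean of 50.5, and a planted list reached percentile 100. No test between the sexes was possible with 1 library each, and no p-value is given. Intervals are 95%: exact binomial for shares, exact Poisson for counts, and a bootstrap over regions (2000 resamples) for medians. They cover counting error or the spread over regions, not the spread between animals, and regions are not independent replicates.

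Named regions and genes followed a rule set before the data were examined, and those named outside it are said to be so. It took the 10 shared regions with the highest value of the lower fold, the 5 regions of highest −log10 q in each list with no region of the other list within 1 kb, and from each gene list up to 4 members with a shared region and up to 2 with a region in a single library. Regions were named by the nearest protein-coding gene within 50 kb or the gene they lay in. Alternatives covered the thresholds (−log10 q of at least 5, fold of at least 5), the overlap that counts as shared, the chance model, the window around gene ends and the background of the lists. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.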

Results

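REST, a zinc-finger repressor that keeps neuronal genes silent outside the nervous system, was mapped by ChIP-seq in mouse placentae labelled male and female at gestation day 15. Each sex was represented by 1 pooled library made from 3 biological replicates, so all differences below are between 2 libraries and have no replicate check. The ChIP libraries were of similar recovered depth, at 39.9 M (male) and 38.9 M (female) reads under the default genome size. The male list held 11540 regions on the nuclear chromosomes and the female list 7469. Median fold enrichment was 3.64 (quartiles 2.96 and 4.95) in the male and 3.91 (quartiles 3.10 and 5.56) in the female list. The median summit held 50 fragments in both.

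The first comparison asked which genes carried REST regions in placenta. Known targets of the RE1 element, the DNA sequence that REST recognises, were covered in both libraries at 41 of 51 genes (80.4%, 95% exact binomial interval 66.9 to 90.2), above all 10000 length-matched random lists, whose median was 33.3%. Ranked by the lower of both folds, as are the members of the lists that follow, the first of these regions lay at Celsr3, a cadherin of axon tract development (fold 29.8 in the male and 26.5 in the female list), Snap25, a SNARE protein of synaptic vesicle fusion (27.9 and 25.0), L1cam, an axonal adhesion molecule (30.5 and 22.3), and Glra1, a glycine receptor subunit (22.3 and 18.9). Stxbp1, another vesicle fusion gene, had a region in the male list alone (fold 4.03, −log10 q 11.3), and 9 list members had a region in neither. With summits required within 1 kb of a gene end, 49.0% of the list was covered in both.

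Among the other neuronal lists, coverage was highest at neuropeptide and secretory granule genes, where 20 of 38 (52.6%) had a region in both libraries, at percentile 99.4 of random lists. In the male library alone the percentile of this list was 88.85, inside the central 95% of random lists, and in the female library alone 99.26. Examples of covered genes were the granins Vgf (fold 19.9 in the male and 18.4 in the female list), Chga (20.5 and 16.8) and Scg2 (17.3 and 14.0), and Resp18 (22.7 and 14.5). These granins are also members of the RE1 target list, as are the covered genes Scg3, Chgb, Ptprn, Ptprn2 and Crh. Coverage without the members shared with that list was not tested. Tph1, an enzyme of serotonin synthesis, had a male region alone (4.47). Synaptic vesicle release genes were covered at 24 of 46 (52.2%, percentile 98.0), with Unc13a, a vesicle priming factor (16.8 and 14.1), Bsn, an active zone scaffold (15.3 and 12.0), and Syt7, a calcium sensor (11.2 and 10.8), after Snap25. In each library alone this list was inside the central 95% of random lists, at percentile 89.4 (male) and 97.385 (female). Snap25 and Unc13a are also RE1 list members, as are Cplx1, Syt4, Syn1, Syp and Stxbp1. Syt1 had a male region alone (3.35). With summits within 1 kb of a gene end the percentiles were 96.8 for neuropeptide and 93.3 for synaptic genes, inside the central 95% of random lists.

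Voltage-gated ion channel genes were covered at 23 of 50 (46.0%, percentile 88.5), neurotransmitter receptor genes at 19 of 56 (33.9%, percentile 32.2) and axon guidance and neuronal transcription factor genes at 20 of 53 (37.7%, percentile 72.5). These shares lay inside the central 95% of random lists, except that channels reached percentile 98.1 against unmatched genes and 98.5 at −log10 q of at least 5, and axon guidance genes 98.0 by nearest gene. With summits within 1 kb of a gene end, coverage was 14.0% for channels (percentile 5.05), 16.1% for receptors (9.20) and 13.2% for axon guidance genes (5.63). Cacng2 (24.1 and 17.4), Kcnc3 (24.3 and 17.2), Cacna1h (19.6 and 17.1) and Cacng3 (20.7 and 17.0) led the channel list. The receptor genes Grin1 (18.6 and 15.8), Chrnb2 (15.7 and 11.8) and Chrm4 (13.1 and 11.1) followed Glra1. The transcription factor genes Lhx3 (25.7 and 17.7) and Pou4f3 (21.7 and 14.6) followed Celsr3 and L1cam. Of the genes named here, Cacna1h, Glra1, Grin1, Chrnb2, Chrm4, Celsr3 and L1cam are also RE1 list members. Regions in a single library lay at Cacna1c (3.35) and Scn5a (2.97), Grm8 (5.99) and Unc5b (3.80) in the male list, and at Glra2 on X (7.64) and Unc5c (4.49) in the female list.

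Genes of REST's own complex were covered at 18 of 24 (75.0%, percentile above 99.9), led by Rest itself (11.01 and 8.89), Rcor1, the corepressor CoREST (7.44 and 8.64), Cdyl (5.01 and 4.95) and Ctdsp1 (4.81 and 4.63). Hmg20a had a male region alone (3.01). Genes of cytosolic ribosomal proteins, a housekeeping list, were covered at 57 of 72 (79.2%), also above all 10000 random lists, whose median was 23.6%. Rps7 (23.6 and 23.3), Rpl7a (20.7 and 21.1), Rps28 (20.7 and 19.5) and Rpl26 (17.9 and 18.4) ranked first by the lower of both folds, with summits within 69 bases of a gene end. Over the shared regions of each list, the lower of both folds had a median of 3.44 at REST complex genes, 3.87 at ribosomal genes and 8.72 at RE1 targets. Rpl36 (3.69) and Rpl8 (3.46) had male regions alone.

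Few genes of the trophoblast and cell marker lists were covered. Of the trophoblast and placental hormone genes 7 of 56 (12.5%, 95% interval 5.18 to 24.1) had a region in both libraries, at percentile 0.060, although assigning each region to the nearest protein-coding gene at any distance moved this to percentile 18.8. The Prl, Psg and Cts members of this list, families of related genes, had no region in either library. The interval and percentile count them as independent genes, and the list without them was not tested. How well reads can be placed among such related genes was not examined. Stra6, the retinol transporter, stood out within the list (17.8 and 11.7), before Glis1 (9.55 and 5.51), Gata2 (4.998 and 4.92) and Ceacam14 (4.33 and 4.17). Flt1, a receptor for vascular growth factors (3.73), and Tpbpa, a spongiotrophoblast marker (3.46), had male regions alone. Endothelial, stromal, decidual and blood cell markers were covered at 3 of 34 (8.82%, percentile 0.100), at Pdgfra (4.27 and 4.95), Esam (3.88 and 3.69) and Cdh5 (3.97 and 2.96). Des (3.29) and Klf1 (2.93) had male regions alone. Imprinted genes were covered at 21 of 52 (40.4%, percentile 80.3), or at 11.5% (percentile 0.86) with summits within 1 kb of a gene end. By the lower of both folds, the first regions were the one shared by Zrsr1 and Commd1 (23.5 and 17.5), of which Zrsr1 lies within an intron of Commd1, the one inside Grb10, a growth restrictor (18.1 and 13.4), and the one at Ube3a (10.8 and 10.8). Ppp1r9a (4.31) and Impact (4.19) had male regions alone.

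**Figure D1:**
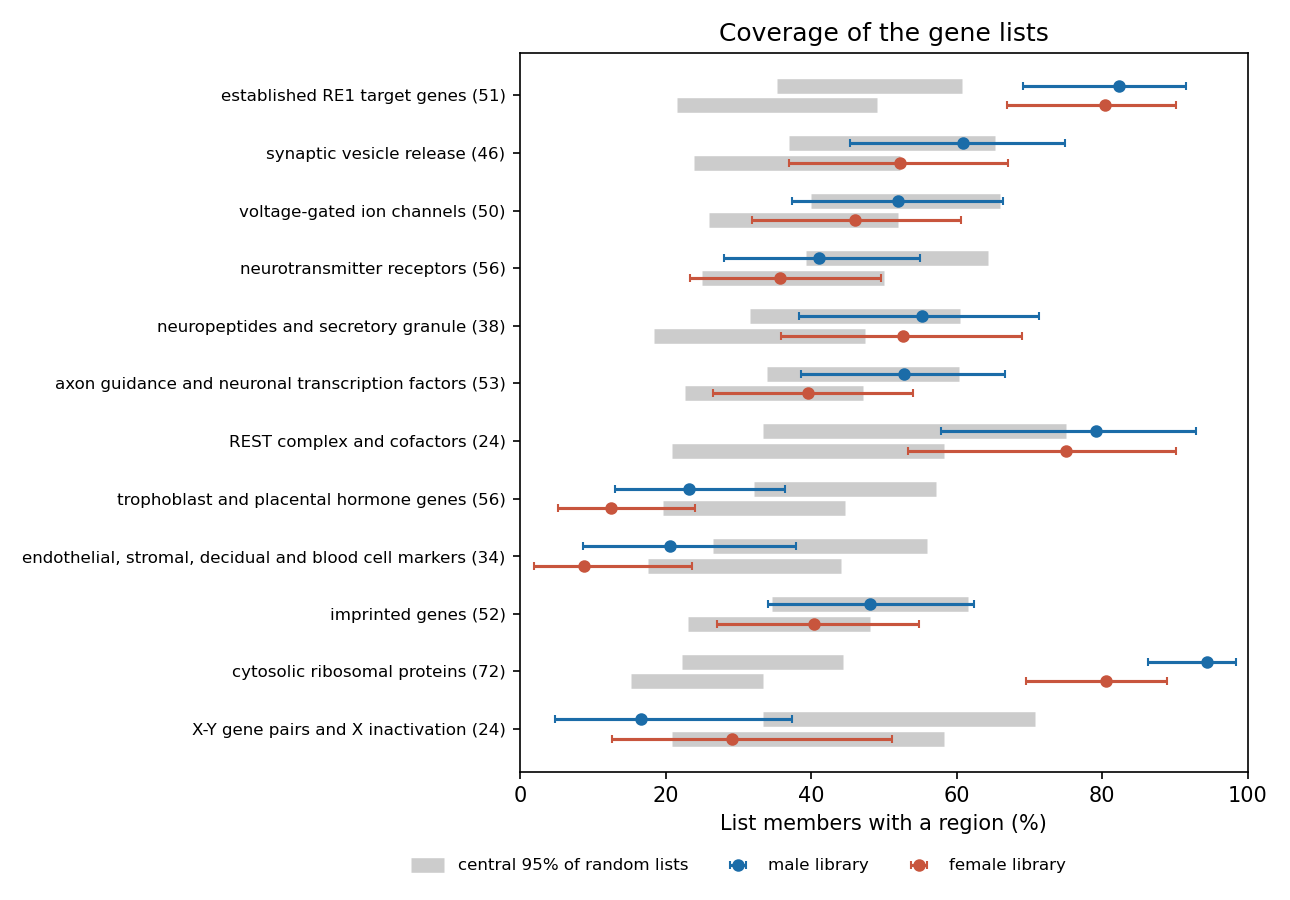
Percent of the members of each gene list (horizontal axis) with a region in the male (blue) or female (red) library; list sizes are in parentheses, bars are 95% exact binomial intervals, and grey bands hold the central 95% of 10000 length-matched random lists. RE1 targets and ribosomal protein genes lie above their bands in both libraries, and trophoblast and vascular, stromal and blood cell genes below them; the X–Y list includes Y genes, so its female share cannot be compared with its band.

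The second comparison asked whether REST occupied the same regions in both sexes. Nearly all female regions were also male regions: 7110 of 7469 (95.2%, 95% interval 94.7 to 95.7) overlapped a male region, whereas 6897 of 11540 male regions (59.8%, 58.9 to 60.7) overlapped a female one. Random placement gave 0.415% of female and 0.274% of male regions, and placement near the ends of random protein-coding genes 8.75% and 5.49%. The regions found in the male list alone were weak, with a median fold of 3.04 and 40 fragments at the summit, against 4.38 and 62 for shared male regions. Male regions overlapped a female one in 13.1% of cases in the lowest decile of −log10 q and in 99.7% in the highest. When the male list was reduced to its 7469 strongest regions, 80.1% of them and 83.1% of the female regions were shared.

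**Figure D2:**
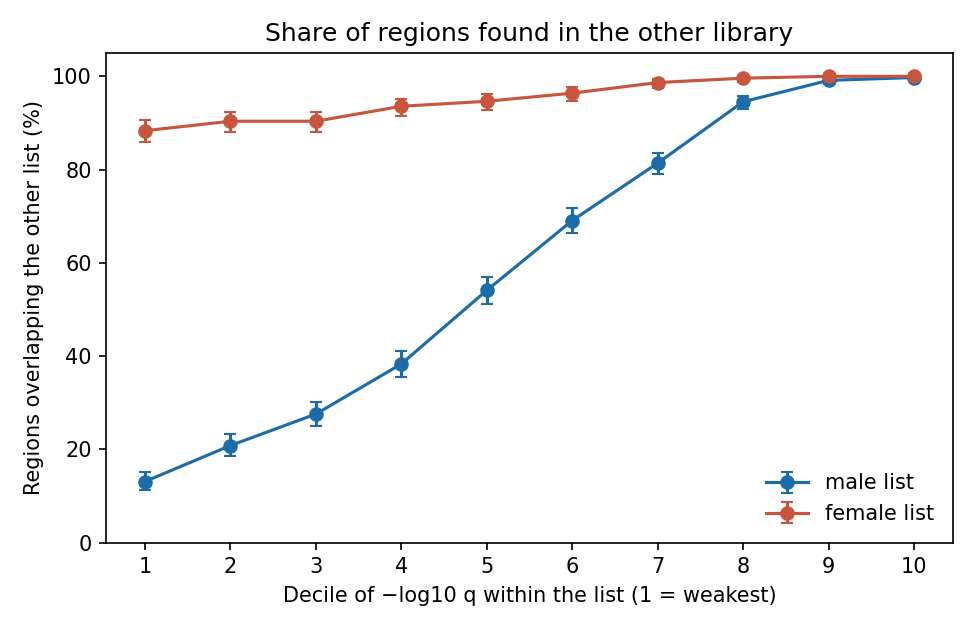
Percent of regions that overlap a region of the other library (vertical axis) by decile of −log10 q within the region's own list (horizontal axis, 1 the weakest), with 95% exact binomial intervals. The male curve climbs from 13.1% to 99.7% and the female curve from 88.3% to 100%.

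Of the 10 shared regions ranked first by the lower of both folds, 1 lay on chromosome 15 at 72567960 to 72569094 (GRCm38), 20.1 kb from the nearer end of Kcnk9, an imprinted potassium channel gene, with folds of 46.5 in the male and 38.6 in the female list. A region on chromosome 6 at 30509327 to 30510116, 13 bases from an end of Ssmem1, had folds of 37.0 and 40.03. Further regions lay inside Erich1 (31.4 and 31.5), Celf4, a neuronal RNA-binding protein (34.6 and 30.5), Huwe1, a ubiquitin ligase gene on X (29.8 and 31.1), Taok1 (29.7 and 32.6) and Pura (29.8 and 29.0), and at the ends of Ncoa4 (31.0 and 30.0) and Micos10 (33.1 and 29.2). The last of the 10, on chromosome 12 at 24424552 to 24425766, had no protein-coding gene end within 50 kb (29.8 and 28.9). These summits held between 222 and 356 fragments, all over 50% of the ceiling of 360 (male) or 342 (female).

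Of the male regions, 3954 had no female region within 1 kb. The 5 with the highest −log10 q were all on the Y chromosome, between 4003524 and 6859031, with folds from 6.79 to 14.7, and none had a protein-coding gene end within 50 kb. The Y regions with folds of 14.7 and 11.3 had a control pileup of 3.20, the lowest of the male list. Outside Y, a set chosen after the values were seen, the strongest lay 23.9 kb from Serhl (fold 7.57), 4 bases from an end of Dnajc15 (6.78), 22.1 kb from Nos1 (7.75), on chromosome 3 with no protein-coding gene end within 50 kb (8.62), and inside B3gnt6 (7.05). Of the female regions, 294 had no male region within 1 kb. The strongest lay 4.38 kb from the olfactory receptor gene Olfr223 (8.91), inside Frmpd2 (7.15), 1.44 kb from Pou4f2, a neuronal transcription factor (8.06), at Gm51425 (5.71), and on chromosome 12 with no protein-coding gene end within 50 kb (7.43). These summits held between 34 and 49 fragments. At Olfr223, Pou4f2 and on chromosome 12 the control pileup was 3.04, at or next to the lowest of the female list.

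The third comparison set the male and female signal side by side at the 6860 paired shared regions. Regions called in a single list have no ratio. A male region alone was found at 11 ribosomal protein genes and at 1 RE1 target gene. The lists were not matched on strength: the lower fold had a median of 8.72 at RE1 targets and 3.87 at ribosomal genes. RE1 target regions held more male than female fragments after scaling for depth and fragment length, at a median log2 ratio of 0.37 (95% interval 0.29 to 0.44), and 45 of 48 regions were higher in the male library. The ratio was 0.37 at axon guidance and neuronal transcription factor genes (0.20 to 0.51), 0.34 at neurotransmitter receptors (0.21 to 0.55) and 0.31 at imprinted genes (0.10 to 0.40). It was 0.30 at neuropeptide (0.05 to 0.40), 0.26 at channel (0.08 to 0.35) and 0.25 at synaptic genes (0.09 to 0.40). The neuronal lists share members with the RE1 targets, so their ratios are not separate results. For ribosomal, REST complex, trophoblast and other lists the values were as follows. It was 0.11 at ribosomal protein genes (0.04 to 0.19), 0.08 at REST complex genes (−0.03 to 0.19) and 0.04 at trophoblast genes (−0.11 to 0.24). The 4 regions of vascular, stromal, decidual and blood cell markers had a ratio of 0.10 (−0.14 to 0.32), and the 5 of X–Y and X inactivation genes −0.13 (−0.54 to 0.17), with 1 higher in the male library. With the ceiling undone and regions over 50% of it left out, the order of the lists changed. The ratio was then 0.47 at RE1 targets (0.39 to 0.55), 0.44 at axon guidance genes, 0.43 at receptors and 0.35 at neuropeptide genes, whose interval included 0. It was 0.23 at synaptic, 0.21 at imprinted and 0.21 at ribosomal genes (0.10 to 0.28), and 0.14 at channels (0.01 to 0.36), below the 0.16 of all such regions. Over all shared regions the median was 0.14 (0.13 to 0.15), and 72.4% of regions were higher in the male library. The authors' fold enrichment also gave 0.14, but the fragments were recovered from it, so this is no separate check. Intergenic regions had a median of 0.25 (0.22 to 0.28) and regions at gene ends 0.12 (0.11 to 0.13). Across regions, log2 folds correlated with a Pearson r of 0.916 and a Spearman rho of 0.829. Both folds share a control, which alone gave an r of 0.157 when female fragments were dealt out at random over the regions. Fragments, without the control, had an r of 0.940 and a rho of 0.865, over regions selected for being in both lists. Paired summits lay a median of 30 bases apart.

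**Figure D3:**
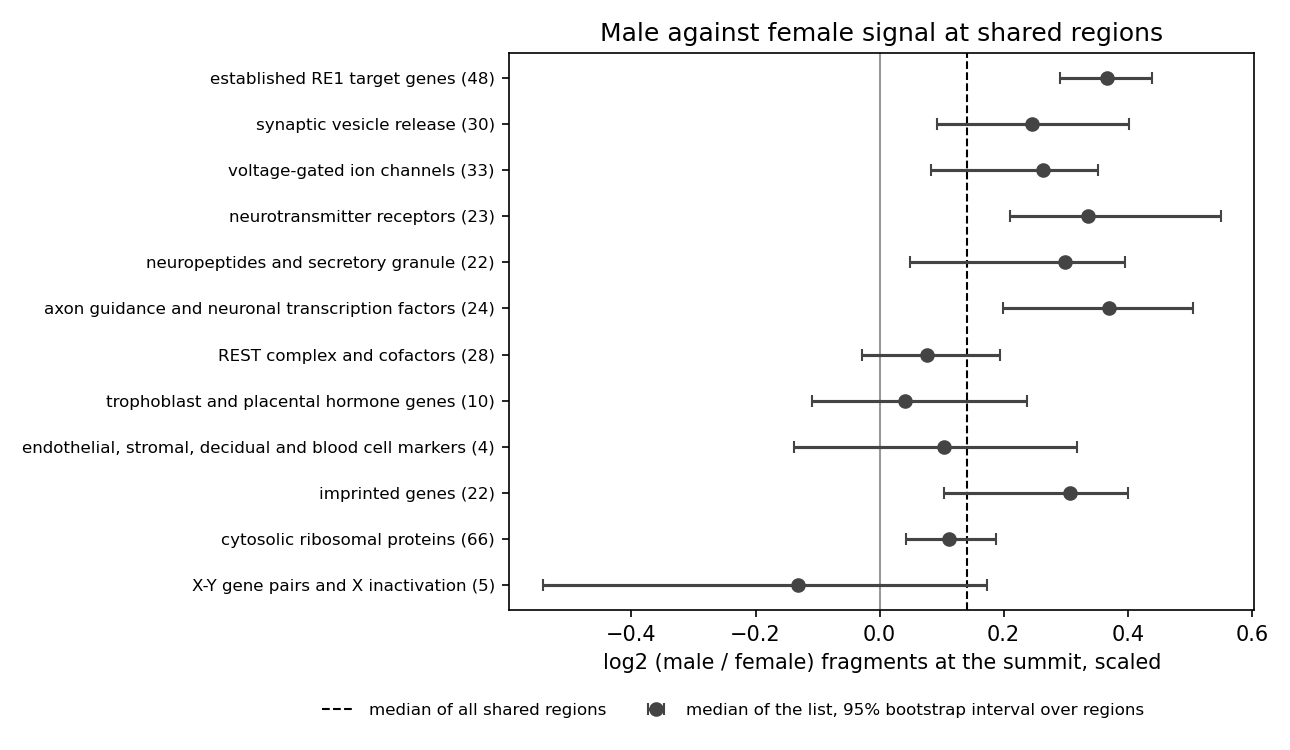
Median log2 ratio of male to female fragments at the summit, scaled for depth and fragment length (horizontal axis), over the shared regions of each gene list (number of regions in parentheses), with 95% bootstrap intervals over regions; the dashed line is the median of all shared regions. RE1 target regions (0.37) lie above ribosomal protein regions (0.11), but lists were not matched on strength and regions called in a single list are left out.

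Most regions lay at genes. Summits within 1 kb of an annotated gene end made up 66.3% of the male (65.4 to 67.1) and 68.6% of the female list (67.5 to 69.6), against 6.10% of random positions. A further 24.2% and 22.3% lay inside genes, and 9.53% and 9.14% between genes, against 51.4% of random positions. Of protein-coding genes of at least 10 kb with a region at an end, 97.8% (male) and 98.9% (female) had it at a single end. The share at gene ends was lower among regions of high fold, at 57.0% in the top decile of the male list against 74.5% in the lowest, and at 65.2% against 79.6% in the female list.

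The sex chromosomes differed between the libraries. X and Y differ in copy number between male and female placenta, so their regions serve as a check of the sex labels. They are not read as a difference in REST binding. The control also appeared common to both lists, and such a control cannot match both sexes on X and Y. The male list held 27 regions on Y and the female list 1. On X the female list held 130 regions, 0.255 of its autosomal rate per Mb (95% Poisson interval 0.213 to 0.303), and the male list 115, or 0.145 of its rate (0.120 to 0.175). On no other chromosome did the female list hold more regions than the male list, and 42 of its X regions (32.3%) had no male overlap, against 4.31% on the autosomes. Shared X regions had a median log2 ratio of −0.03 (−0.11 to 0.06), and X minus autosomes was −0.17 on the log2 scale (−0.24 to −0.08). That is a male to female ratio of 0.89 relative to autosomes. It falls short of the drop that X copy number alone would give, so these ratios check the labels in direction only. X regions found in a single list are not part of these values. Among X–Y gene pairs and X inactivation genes, 4 of 24 had a region in both libraries, but 10 members lie on Y, which a female library lacks, so the rank of this list among random lists is not read. The male list had a region at 0 of these 10 as well (upper limit 30.8%). Of its 14 X members, 4 had a region in the male list (28.6%, 95% interval 8.39 to 58.1) and 7 in the female list (50%, 23.0 to 77.0). Shared regions lay at the helicase gene Ddx3x (15.9 in the male and 16.1 in the female list), Usp9x (4.60 and 5.21), the histone demethylase gene Kdm6a (3.85 and 5.22) and Ftx (3.32 and 4.81). A further 3, among them Eif2s3x (4.62) and Jpx, an activator of Xist (3.54), had a female region alone.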

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

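The peaks on mitochondrial DNA stand outside the comparisons, which used the nuclear chromosomes, and are listed because they are signal in sequence that no comparison used. The male list had 4 such regions, with folds from 1.74 to 2.40, and the female list had 4, with folds from 1.61 to 1.90. Their control pileups reached 104 and 88, against medians of 11 and 10.6 at nuclear regions.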

How the results depend on the processing

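Except for 3 measures of the shared signal, all alternatives were chosen before the data were examined. The ratio of region counts and the median log2 ratio of shared regions, the results checked for a change of direction, kept theirs. Of 140 values, 86 stayed close to the main value. For a count or a ratio of counts this means within 1.5 times it, and for a share, rate or median within its interval. Chance overlaps had to stay within the range of random placements, and percentiles on the same side of the central 95% of random lists. Some of the 86 could hardly change: no intervals overlap, so counting every line changes nothing, and counting all sequences adds only the mitochondrial regions. Most of the moved values follow from the construction of the alternative, which counts fewer or more regions. For the others the cause was not tested. No paired analysis was possible because each sex has 1 library.

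A fold of at least 5 left 2844 male and 2298 female regions, with median widths of 646 and 500.5 bases and median folds of 7.51 and 7.42. At −log10 q of at least 5 these were 453 and 360 bases, and 4.12 and 4.36. Shared male and female regions were 48.4% and 74.7% with at least 50% of each region covered, 50.9% and 78.7% with summits within 100 bases, 65.7% and 96.1% within 1 kb, 62.8% and 92.4% at −log10 q of at least 5, 72.2% and 89.5% at fold of at least 5, and 80.1% and 83.1% with the male list reduced. Chance overlap was 0.512% and 0.788% with all regions moved together by 100 kb to 1 Mb, and 5.49% and 8.75% near gene ends.

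The median log2 ratio of shared regions was 0.44 for −log10 q, 0.13 at −log10 q of at least 5 and, as an alternative added after seeing the data, 0.18 for scaled fragments with the ceiling undone. Summits at gene ends were 57.4% and 61.0% within 500 bases, 80.8% and 82.3% within 5 kb, 61.7% and 64.4% for protein-coding genes, and 67.7% for male regions at −log10 q of at least 5.

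With summits within 1 kb of a gene end, coverage was 49.0% for RE1 targets, 34.8% for synaptic, 14.0% for channel, 16.1% for receptor, 13.2% for axon guidance, 3.57% for trophoblast and 11.5% for imprinted genes. At −log10 q of at least 5 it was 23.1% for imprinted and 63.9% for ribosomal genes, and by nearest gene 66.7% for ribosomal genes. Percentiles that changed side were, within 1 kb, 93.3 for synaptic, 96.8 for neuropeptide and 0.860 for imprinted genes; by nearest gene, 98.0 for axon guidance and 18.8 for trophoblast genes; against the unmatched background, 98.1 for channels and 5.11 for X–Y genes, a list not read because of its Y members; and at −log10 q of at least 5, 98.5 for channels.

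The 4 lists at the extremes kept their side in every alternative run: RE1 targets, REST complex and ribosomal genes above, and vascular, stromal, decidual and blood cell markers below. Counting every line gave identical counts, since no intervals overlap. The 6 alternatives for the RE1 motif and the removal of repeats were not run, since they need a genome sequence. Male regions without a female overlap had a median of 40 fragments, and how many would be called at another depth was not tested.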

Other observations

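The tests of depth, control, yield, pseudogenes, transcription and fragment length, and the set of RE1 against ribosomal regions, were chosen only after the result was seen; for transfer RNA genes, the ceiling and the subtracted control, related values without these restrictions had been seen. Transfer RNA genes, which RNA polymerase III transcribes, often had a region within 500 bases. In the male list this held for 96 of 408 (23.5%, 95% interval 19.5 to 28.0) and in the female list for 49 (12.0%, 9.02 to 15.6), against 2.45% and 1.35% of windows moved by 10 kb. The share was 5.54% and 3.42% for microRNA genes, against 1.51% and 1.26% of moved windows, 2.39% and 1.49% for small nuclear RNA genes, against 0.647% and 0.349%, and 10.7% and 7.40% for long noncoding RNA genes, against 6.67% and 4.42%. Small nucleolar RNA genes had 1.34% (0.798 to 2.11) and 0.970% (0.518 to 1.65), with intervals overlapping those of the moved windows at 0.821% and 0.560%. For pseudogenes it was 0.463% and 0.282%, below the moved windows at 1.04% and 0.654%. Among the established RE1 targets, and chosen after their values were seen, the noncoding genes Mir132 (fold 17.6 in the male and 13.0 in the female list) and Mir9-3hg (7.06 and 4.67) had shared regions. Mir124-2hg, also a noncoding member of that list, had a region in neither library.

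Gene families, chosen after their coverage was seen, differed widely. Regions were present in both libraries at 73.2% of 41 Zbtb transcription factor genes, 60.0% of 30 Mediator genes and 57.1% of 35 Vps vesicle sorting genes, against 31.8% of all protein-coding genes. Of 25 Prl genes, the prolactin-related hormones of the placenta, 0 had a region in either list (upper limit 13.7%), and the same was true of 22 Pcdhb, 56 Krtap and 42 Defb genes. Of 1110 olfactory receptor genes 3 were covered in both. For these families too, how well reads can be placed among related genes was not examined. Of 39 Hox genes, 7 had a region in the male list (17.9%, interval 7.54 to 33.5). In the female list 0 had one (upper limit 9.03%), and these intervals overlap. Regions without a female overlap made up 40.2% of the whole male list. Whether Hox genes differ between the libraries was not tested, so no difference in binding is read from them.

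The male list was longer, at 1.55 times the female count. Depth and fragment length do not account for it as a whole, since scaled fragments still had a median log2 ratio of 0.14 (0.13 to 0.15). A different control is argued against as well, because at 888 summits within 5 bases of each other the control pileups differed with 0.0184 of the variance of independent counts. A higher yield of the male immunoprecipitation and a difference between the sexes cannot be told apart with 1 library per sex.

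Regions at ribosomal protein genes are a second pattern, and the design gives no biological explanation to test. Reads shared with processed pseudogenes stay open. Of 298 ribosomal protein pseudogenes 0.336% had a female region, but so did only 0.282% of all pseudogenes. How reads matching several places were aligned is not known here, so a low share does not decide the question. Signal that follows transcription stays open: 12.5% of trophoblast and hormone genes had a female region, but no RNA was measured, and the percentile of this list moved to 18.8 when regions were assigned to the nearest gene. Transfer RNA genes over 5 kb from protein-coding gene ends had female regions at 10.96% (7.67 to 15.1) against 1.495% of moved windows, but small nucleolar RNA genes did not stand apart from theirs and activity was not measured, so signal at active gene ends of every kind stays open. Whether REST itself is bound at ribosomal protein genes, or at the REST complex genes, stays open without the RE1 motif.

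The third pattern is the higher male to female ratio away from gene ends. The ceiling on tall regions could compress gene-end regions, but with it undone and regions over 50% of it left out, intergenic regions still exceeded gene-end regions by 0.13 (0.08 to 0.17). With the control pileup subtracted as well the difference was 0.13 (0.09 to 0.19), and over all shared regions it was 0.13 (0.09 to 0.16), beyond the 0.07 that the fragment lengths allow. A joint effect of fragment length with the ceiling or the background was not tested. With the ceiling undone, RE1 target regions exceeded ribosomal ones by 0.27 (0.14 to 0.41). Only regions called in both lists enter, which leaves out male regions without a female call, and strength was not matched. Channel genes were at 0.14 (0.01 to 0.36) and ribosomal ones at 0.21 (0.10 to 0.28), with overlapping intervals, and without this step their order was the opposite (0.26 and 0.11). Sex and the immunoprecipitation of 1 pool both stay open and untested.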
